A study of Homo sapiens with 220 samples.

How the data were processed

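Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where MYC, MED1 and the glucocorticoid receptor (GR) sat on the genome of human breast cancer cell lines. MYC is a transcription factor, MED1 is a subunit of the Mediator coactivator complex, and GR is the nuclear receptor that binds glucocorticoid hormones. Of the 220 samples of the series, 24 had processed files in the material used here, and the remaining samples were not analysed here. The 24 libraries formed 8 groups of 3: MYC in untreated BT549 cells, MYC in untreated MCF7 cells, MYC and MED1 in BT549 cells given vehicle (labelled Veh) or dexamethasone (labelled Dex), and 2 groups of GR libraries in BT549 cells. Per the labels' protocols, Dex was given at 0.5 µM for 2 h, cells were crosslinked with disuccinimidyl glutarate and then formaldehyde, chromatin was sheared by sonication, and libraries were sequenced as paired ends.

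Each file was a list of peaks called in 1 library. Per the submitters' processing notes, the tools were bcl2fastq, SAMtools, MACS2 and HOMER and the genome build was hg38 (GRCh38). Versions, the aligner, the control library behind each list, filters and any scaling are not given in the sources used here. For every peak the deposited lists held an integer score, a fold enrichment ratio over background at the summit, and −log10 values of the p-value and of the q-value, as the authors' peak caller wrote them. The deposited −log10 q values began just above the level that corresponds to a q-value of 0.05, the largest q-value in any list being 0.0499. These values belong to the authors' own peak calls, were made library by library, and were used to rank or filter peaks within a list. Between lists only the highest folds of the BT549 MYC lists were set side by side, to describe the peak calls. The lists hold no read counts, so the sequencing depth of each library is unknown and no interval that needs it was given. A longer list can come from deeper sequencing or better enrichment as well as from more binding.

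Peaks on chromosomes 1 to 22 and X were kept, which left out between 4 and 51 peaks per library. For each comparison the peak intervals of its 6 libraries were merged wherever they overlapped by at least 1 bp. A merged region was called group-only when it held a peak in 3 of 3 libraries of one group and 0 of 3 of the other. Within a list, each peak received a percentile by its −log10 q, and a region's strength was the mean percentile over the libraries that held it. The gene table used was that of GRCh38.p14 with 19970 protein-coding genes. It gives no strand, so the planned distance to a transcription start was replaced by the distance to either end of a gene. A peak or region whose summit lay within 1 kb of either end is called a gene-end peak or region here. A region was near a gene when any part of it lay in the gene or within 50 kb of it. Only the nearest gene of the strongest regions was found by the distance from the summit.

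Peak numbers, gene-end shares and shares at GR regions were compared between groups of 3 libraries with exact two-sided permutation tests of the difference of means. With 3 against 3 libraries the smallest p such a test can give is 0.1, so none of these tests could reach 0.05. The labels number the libraries as biological replicates without saying whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Counts of group-only regions were set beside the counts from the other 9 splits of the 6 libraries. Shares of regions were compared with Fisher's exact test over regions, which are not independent replicates.

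The gene lists were fixed before the data were examined and held 11 groups: glucocorticoid targets (40 genes), MYC core targets (40), estrogen receptor targets (30), luminal identity (30), mesenchymal and basal genes (35), the AP-1 family (14), inflammatory and NF-kB genes (22), cell cycle and E2F genes (22), clock and metabolic genes (20, of which 19 matched the gene table), housekeeping genes (20) and markers of other tissues (36). For each list and direction, the number of genes near at least 1 group-only region was compared with 10000 random lists of as many genes matched on how many merged regions lay near them, with a two-sided permutation p adjusted by Benjamini-Hochberg over the 22 tests of a comparison. Genes with no region near them in a comparison were left out. Genes that are neighbours can share a region. The genes named in the text followed a rule written before the data were examined: a set of genes named in every case (FKBP5, PER1, TSC22D3, SGK1, KLF9, DUSP1 and MYC for Dex; ESR1, GREB1, TFF1, GATA3, FOXA1, KRT8, VIM, ZEB1, AXL, FOSL1 and MYC for the cell lines; NCL, NPM1, ODC1 and CAD for MYC), the 10 strongest group-only regions per direction that had a gene within 50 kb, and up to 4 genes per list with the most group-only regions. For GR the 10 strongest regions found in all 3 human lists were added.

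For all 6 GR libraries the title and the treatment tag contradicted each other, one saying Dex where the other said Veh, and no attempt was made to decide between them. The 3 lists whose titles said Veh held peaks on chromosome arms of the fruit fly (2L, 2R, 3L and 3R) and none on chromosomes 1, 3 or 5 to 22, so the planned comparison between GR groups was not made. The 3 GR lists with human coordinates, titled Dex and tagged Veh, were used as a map of GR positions whose treatment is unknown. A GR region was a merged region with a peak in at least 2 of these 3 lists, in place of the planned rule over both GR groups. The planned counts of sequence motifs were not run, because no genome sequence was used here.

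The counting of group-only regions was tested on simulated data. Of 200 planted regions present in every library of one group and in none of the other, 100% were recovered, and with a presence chance of 0.9 in one group and 0.05 in the other between 60.5% and 61% were recovered, where arithmetic gives 62.5%. Regions simulated with no difference between groups but with the real list lengths gave 5350 MCF7-only and 636 BT549-only regions for the cell lines, 501 Dex-only and 200 Veh-only regions for MYC, and 594 and 289 for MED1. Each simulated region kept its real number of libraries, so the real group-only regions, each held by exactly 3 libraries, raised these counts. They are therefore no estimate of what list length alone gives. Of 200 random gene lists per comparison, between 0.5% and 2.5% had p under 0.05. In planted lists each gene was given a region with a chance of 60%, on top of any it already had, so these lists were enriched in every comparison. For the Dex-only regions of MYC and MED1, which 21.4% and 20.7% of the genes tested (18175 and 17381 genes with any merged region nearby) had nearby, the planted lists were detected in 100% of 50 trials. For MCF7-only regions, which 77.6% of the 19327 genes tested had nearby, the planted lists were detected in 60% of 50 trials. The power to find an enrichment was thus lower there, and the power to find a depletion was not tested.

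Alternatives were lists of equal length (each list shortened to the length of the shortest of its comparison, keeping the highest −log10 q), a stricter threshold (−log10 q of at least 5), windows of 100 bp either side of each summit in place of whole peaks, gene ends within 3 kb, gene windows of 20 kb, Fisher's exact test without matching, GR regions in all 3 lists, leaving out each library in turn, and the replicate number as a block. Counting all group-only regions near a list's genes, in place of genes with at least 1, was added after seeing the data. In these counts a region near several genes of a list counted once for each gene, so neighbouring list genes can raise them. Over all pairs of the 24 lists, identical intervals made up at most 0.00628% of the shorter list for the 24 pairs within a group and 0.00734% for the 252 pairs between groups, so no list appeared to be deposited again under another name. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.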

Results

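The data were lists of ChIP-seq peaks from 24 libraries of breast cancer cell lines. BT549 is a triple-negative breast cancer line, that is, one that lacks the estrogen receptor, the progesterone receptor and HER2 amplification, and MCF7 is an estrogen receptor-positive line. MYC was mapped in untreated cells of both lines, and MYC and MED1 were mapped in BT549 cells given vehicle or the synthetic glucocorticoid dexamethasone (Dex, 0.5 µM for 2 h), with 3 libraries per group. GR was mapped in BT549 cells as well, and 3 of its lists had human coordinates. The human lists held between 32599 and 71779 peaks for MYC, between 40873 and 54259 for MED1 and between 2527 and 4241 for GR on chromosomes 1 to 22 and X. Read depth is unknown from the lists.

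**Figure D1:**
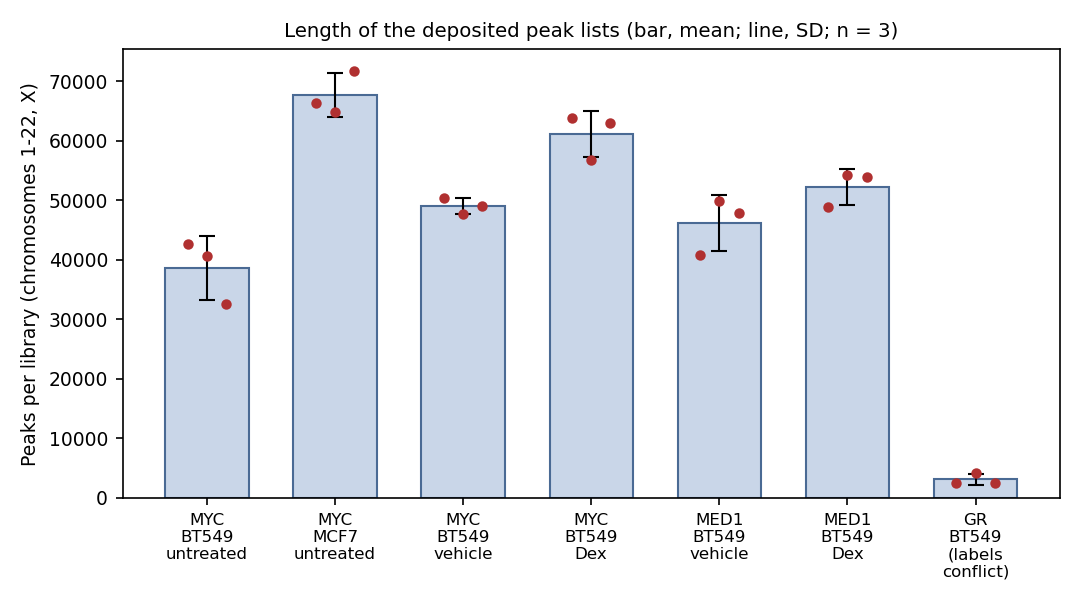
Peaks per library (vertical axis, number on chromosomes 1 to 22 and X) for the 7 groups with human coordinates; bars are means of 3 libraries, lines are SDs and points are single libraries. The MCF7 lists (64868 to 71779 peaks) lie above the untreated BT549 lists (32599 to 42740 peaks), and the GR lists hold at most 4241 peaks.

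The first comparison asked where MYC sits in an estrogen receptor-positive and in a triple-negative line. Among regions called group-only or held by all 6 libraries, MYC regions at gene ends were mostly shared and those elsewhere mostly group-only. Of 109002 merged regions, 15005 held a peak in all 6 libraries, 30653 were MCF7-only and 10169 were BT549-only. Gene-end regions made up 55.4% of the regions shared by all 6 libraries, against 4.85% of MCF7-only and 8.15% of BT549-only regions. The shared regions were also stronger and wider, with medians of percentile 73.6 and 923 bp, against 58.2 and 523 bp for MCF7-only and 53.1 and 638 bp for BT549-only regions. The classes were not matched on either. Within BT549 a like contrast appeared, 32.9% of MYC regions in all 6 Dex and vehicle libraries against 11.0% of Dex-only ones. ESR1, which encodes the estrogen receptor, had 22 MCF7-only and 0 BT549-only regions within 50 kb, whereas EGFR, a growth factor receptor gene on the mesenchymal and basal list, had 1 MCF7-only and 7 BT549-only regions. Genes of the mesenchymal and basal list lay near BT549-only regions more often than matched random genes did.

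Some luminal and estrogen-induced genes had many MCF7-only regions, although the planned list tests did not pass for either group. Next to ESR1, the keratin gene KRT8 had 16 MCF7-only regions and its neighbour KRT18 had 12, GREB1, an estrogen-induced gene, had 10, and TFF1, also estrogen-induced, had 8, with no BT549-only region at any of these 4 genes. The luminal transcription factor genes FOXA1 and GATA3 had 7 and 5 MCF7-only regions against 1 and 0 BT549-only regions. At ESR1 (chromosome 6, 151656672 to 152129619) the 3 MCF7 libraries had peaks in 28, 26 and 25 regions and the BT549 libraries in 3, 3 and 2. At TFF1 (chromosome 21, 42362282 to 42366535) the MCF7 libraries had peaks in 11, 10 and 10 regions and none of the BT549 libraries had any. The strongest MCF7-only region at ESR1 lay in the gene body (chromosome 6, 151703007 to 151703674), and that at GREB1 also lay in the gene body (chromosome 2, 11498421 to 11499122). GRHL2, an epithelial transcription factor gene, had group-only regions of both kinds, 13 in MCF7 and 6 in BT549.

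All 30 genes of the luminal list and all 30 of the estrogen receptor target list had an MCF7-only region nearby, where 28.1 and 27.5 were expected from matched random lists (adjusted permutation p = 0.510 and 0.353). These counts could hardly exceed the expectation, since 15005 of the 19970 protein-coding genes had an MCF7-only region within 50 kb. With peak lists of equal length both lists passed, with 28 of 30 genes each against 21.4 and 20.1 expected (adjusted permutation p = 0.0176 and 0.0110). Counted as regions, once for each list gene nearby, the luminal list had 181 MCF7-only regions against 125 expected and the estrogen receptor targets had 150 against 102 (adjusted permutation p = 0.00147 for both, each unadjusted p being the smallest that the permutations can give). The neighbours KRT8 and KRT18 can share regions in this count. Near BT549-only regions lay 9 luminal genes against 16.5 expected, which did not pass the adjustment (adjusted permutation p = 0.0726), and the alternatives disagreed: it passed with gene windows of 20 kb (4 against 12.5, adjusted permutation p = 0.00587) and counted as regions (17 against 37.8, adjusted permutation p = 0.0257), and not with lists of equal length (17 genes against 19.9, adjusted permutation p = 0.772) or in Fisher's exact test without matching (9 against 11.1, adjusted p = 0.837).

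The mesenchymal and basal list had 33 of 35 genes near a BT549-only region, against 15.3 expected and a middle 95% of 10 to 21 for random lists (adjusted permutation p = 0.0044, the smallest that the permutations can give). After EGFR, the rule of up to 4 genes per list named THY1 with 5 BT549-only regions, TGFBI with 5 and SPARC with 4. Ties went to the gene with the stronger region, so members not named may have as many as SPARC. The markers VIM and AXL had 2 BT549-only regions each, against 1 and 2 MCF7-only regions, and ZEB1 had 1 against 3. Inflammatory and NF-kB genes lay near BT549-only regions in 13 of 22 cases against 8.15 expected (adjusted permutation p = 0.272). This list passed with windows of 20 kb (13 against 5.10, adjusted permutation p = 0.0044) and counted as regions (30 against 13.9, adjusted permutation p = 0.0194), and not with lists of equal length (12 against 10.5, adjusted permutation p = 1) or in Fisher's exact test without matching (13 against 8.11, adjusted p = 0.180). The cytokine genes CXCL1 and IL6 had 4 and 3 BT549-only regions and no MCF7-only region.

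No other group passed the test. Genes near BT549-only regions numbered 22 of 40 for glucocorticoid targets, 11 of 40 for MYC core targets, 11 of 30 for estrogen receptor targets, 9 of 14 for the AP-1 family, 4 of 22 for cell cycle genes, 9 of 19 for clock and metabolic genes, 6 of 20 for housekeeping genes and 11 of 33 for markers of other tissues, with adjusted permutation p of 0.353 or more. Markers of other tissues lay near MCF7-only regions in 29 of 33 cases against 23.9 expected (adjusted permutation p = 0.272). The remaining lists near MCF7-only regions had adjusted permutation p of 0.353 or more, with 36 of 40 glucocorticoid targets, 28 of 40 MYC core targets, 27 of 35 mesenchymal and basal genes, 13 of 14 AP-1 genes, 17 of 22 inflammatory, 17 of 22 cell cycle, 17 of 19 clock and metabolic and 15 of 20 housekeeping genes. The core MYC targets NCL, NPM1 and CAD, which serve ribosome assembly and pyrimidine synthesis, each had 3 regions shared by all 6 libraries and a gene-end peak in both lines; NCL had 1 MCF7-only region, CAD had 2, and NPM1 had 3 MCF7-only and 3 BT549-only regions. ODC1, which encodes a polyamine synthesis enzyme, also had 3 shared regions, and 9 MCF7-only regions. The MYC gene itself had 1 group-only region in each line, and FOSL1 had 1 MCF7-only and 2 BT549-only regions.

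The 10 strongest MCF7-only regions all lay on chromosome 20 (7 regions, near DOK5, RIPOR3, BCAS1 and CYP24A1) and on chromosome 17 (3 regions, near BRIP1, NACA2 and BCAS3). The first of them lay 18946 bp from DOK5 (chromosome 20, 54456260 to 54457045). The 10 strongest BT549-only regions lay on 5 chromosomes, near GARNL3, ANK1, KIF13B, JUN, SLC43A2, NSMCE2, ANKFY1, MSRA, TNIK and OLFML2A. The one near JUN, an AP-1 gene, lay 25225 bp away outside any gene (chromosome 1, 58755188 to 58755993).

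The MCF7 lists were longer, with 67682 ± 3630 peaks against 38663 ± 5355 (SD, n = 3 each, exact permutation p = 0.1). Gene-end peaks made up 19.1% ± 0.909 of the MCF7 peaks and 31.3% ± 3.04 of the BT549 peaks (SD, n = 3 each, exact permutation p = 0.1). With lists of equal length there were 13222 MCF7-only and 11797 BT549-only regions, so most of the excess of MCF7-only regions went with list length. The other 9 splits of the 6 libraries gave at most 234 group-only regions in all, against 40822 for the split by line.

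**Figure D2:**
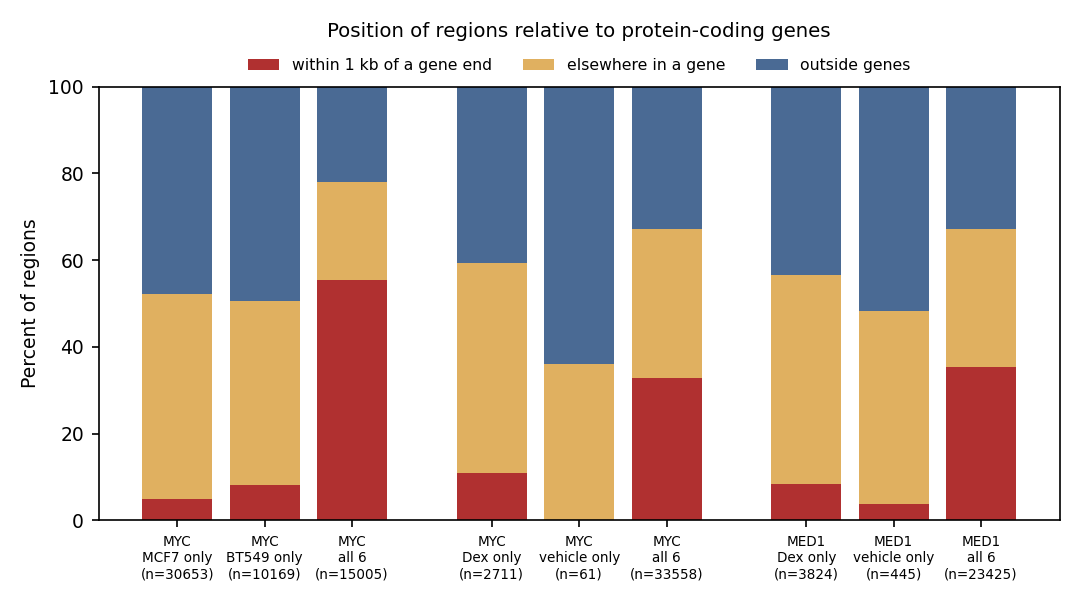
Percent of regions (vertical axis) whose summit lay within 1 kb of either end of a protein-coding gene (red), elsewhere in a gene (yellow) or outside genes (blue), for each class of region in the 3 comparisons. Gene-end regions make up 55.4%, 32.9% and 35.4% of the regions found in all 6 libraries and at most 11.0% of any group-only class.

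The second comparison asked how MYC occupancy in BT549 differed after 2 h of Dex. With the full lists and windows of 50 kb, MYC regions found only with Dex lay near known glucocorticoid target genes more often than near matched random genes, foremost at ZBTB16, FKBP5 and TSC22D3; the call was lost with windows of 20 kb (18 genes against 9.26, adjusted permutation p = 0.0704) and with lists of equal length (10 against 5.11, adjusted permutation p = 0.964). Few regions were found only with vehicle. Of 75934 merged regions, 33558 held a MYC peak in all 6 libraries, 2711 were Dex-only and 61 were Veh-only. At FKBP5, which encodes a GR co-chaperone and is a classic glucocorticoid-induced gene, the Dex libraries had MYC peaks in 19, 15 and 18 regions and the Veh libraries in 4, 5 and 4. Of 40 glucocorticoid targets, 24 lay near a Dex-only region against 12.7 expected from matched random lists.

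At the glucocorticoid targets with the most Dex-only regions, the strongest of these lay away from gene ends. FKBP5 (chromosome 6, 35573590 to 35728583) had 7, the strongest in the gene body (35688675 to 35689533). ZBTB16, a zinc finger transcription factor gene, had 8, the strongest in its gene body (chromosome 11, 114178846 to 114180136). TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein GILZ, had 4, the strongest 34120 bp outside the gene (chromosome X, 107678834 to 107679643). The phosphatase gene DUSP1 had 3, the clock gene PER1 had 2, the kinase gene SGK1 had 1 and the transcription factor gene KLF9 had 0, and none of these genes had a Veh-only region. KLF9 had MYC peaks in 6, 5 and 7 regions of the Dex libraries and in 3, 4 and 3 of the Veh libraries. The MYC gene, NCL, NPM1 and CAD had no group-only region, and ODC1 had 1 Dex-only region at its gene end.

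The count of glucocorticoid targets stood outside the middle 95% of matched random lists, 8 to 18 genes (adjusted permutation p = 0.0044, the smallest that the permutations can give). The call did not hold with gene windows of 20 kb or with lists of equal length, and held in Fisher's exact test without matching (24 against 8.52, adjusted p = 2.85e-06) and counted as regions (49 against 18.8, adjusted permutation p = 0.0044). At equal lengths the count of regions was 25 against 5.97 (permutation p = 0.0002, not adjusted). The other 10 lists had an adjusted permutation p of 1. Genes near Dex-only regions numbered 10 of 40 MYC core targets, 9 of 27 estrogen receptor targets, 10 of 30 luminal genes, 12 of 35 mesenchymal and basal genes, 6 of 14 AP-1 genes, 5 of 22 inflammatory genes, 3 of 22 cell cycle genes, 5 of 19 clock and metabolic genes, 5 of 20 housekeeping genes and 4 of 30 markers of other tissues. No list gene lay near a Veh-only region.

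The 10 strongest Dex-only MYC regions lay near MIOS, PARD6B, MMP20, ZNF366, GNG12, MEGF6, PTPRS, FKBP5, NREP and PYGB. They reached mean percentiles of 74.6 to 77.3 within the Dex lists, and the median over all Dex-only regions was 28.4, against 68.4 for regions in all 6 libraries. Gene-end regions made up 11.0% of Dex-only regions, 0 of the 61 Veh-only regions and 32.9% of the regions in all 6 libraries (Fisher's exact p = 1.97e-145 for Dex-only against all 6). The strongest Veh-only region, in the CDC42BPA gene body on chromosome 1, had a mean percentile of 38.4, and the others of the first 10 lay near PRKG1, RDX, FBXO32, GARIN1A, ARHGAP26, ARHGAP6, B3GALT5, ARID4B and LAMB4.

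Dex libraries had 61153 ± 3894 MYC peaks and Veh libraries 49054 ± 1333 (SD, n = 3 each, exact permutation p = 0.1). Gene-end peaks made up 25.0% ± 0.990 and 29.0% ± 0.554 of them (SD, n = 3 each, exact permutation p = 0.1). With lists of equal length there were 1041 Dex-only and 277 Veh-only regions, and gene-end shares differed by -1.02 percentage points. A count over fewer libraries is looser: without Dex replicate 2 there were 5226 Dex-only regions, without Dex replicate 3 there were 4179, and leaving out any 1 library gave 110 to 207 Veh-only regions. Windows around summits in place of whole peaks gave 2692 Dex-only and 408 Veh-only regions. The other 9 splits gave at most 597 group-only regions in all, against 2772 for the split by treatment. A background without Dex was measured the same way in BT549. MYC libraries of vehicle-treated against untreated cells gave 3815 Veh-only and 308 untreated-only regions, or 1324 and 635 with lists of equal length. The number of Dex-only regions was thus not larger than a difference between library sets that involved no Dex. The highest folds were 30.8 to 33.6 in untreated, 81.0 to 116 in vehicle and 121 to 140 in Dex lists. Vehicle and untreated sets may therefore differ in ways that Dex and vehicle sets do not, and this background cannot decide what Dex against vehicle holds without Dex.

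**Figure D3:**
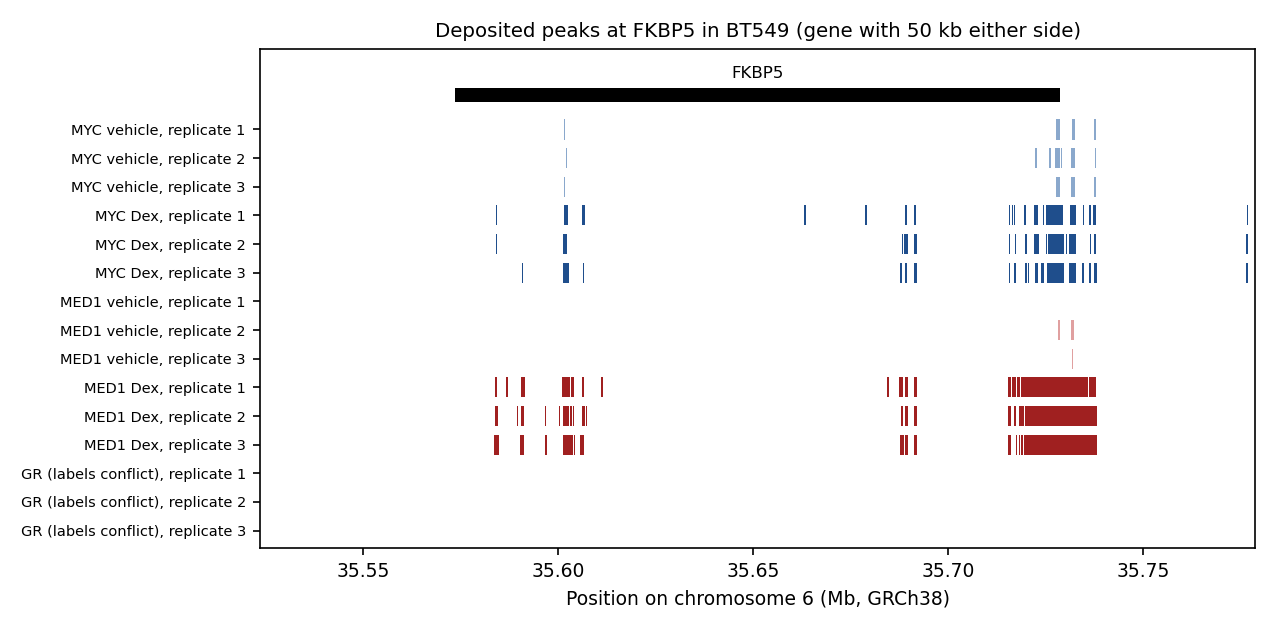
Peaks in each BT549 library (rows) along chromosome 6 (horizontal axis, Mb) at FKBP5 with 50 kb on either side; coloured bars are deposited peaks drawn to scale and the black bar is the gene. Peaks of neighbouring libraries merge into regions: MYC peaks lie in 4 or 5 merged regions in Veh libraries and in 15 to 19 in Dex libraries, MED1 peaks in at most 1 and in 12 to 14, and the GR lists hold none.

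The third comparison asked the same for MED1, a subunit of Mediator. Dex-only MED1 regions also lay near glucocorticoid targets, and they included some of the strongest regions in the lists. Of 73056 merged regions, 23425 held a MED1 peak in all 6 libraries, 3824 were Dex-only and 445 were Veh-only, the last count being 673 with lists of equal length and 1039 with windows around summits. At FKBP5 the Dex libraries had MED1 peaks in 13, 14 and 12 regions and the Veh libraries in 0, 1 and 1. Of the 40 glucocorticoid targets, 27 lay near a Dex-only MED1 region against 14.1 expected and a middle 95% of 9 to 19 (adjusted permutation p = 0.0044, the smallest that the permutations can give).

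The strongest Dex-only MED1 region lay in the body of ZBTB16 (chromosome 11, 114175882 to 114181737) with a mean percentile of 99.9 within the Dex lists, and ZBTB16 had 11 Dex-only regions in all. The next lay 24026 bp from KLF9 (chromosome 9, 70438003 to 70439505), a gene with 3 Dex-only regions. The others of the first 10 lay near MAFB, LOC124904930, MIOS, GNG12, TRPM3 (2 regions), ARRDC1 and N4BP2, all at mean percentiles of at least 98.4. Among the glucocorticoid targets, ERRFI1, which encodes an inhibitor of EGFR signalling, had 11 Dex-only regions, the metallothionein gene MT2A had 9, FKBP5 had 8 and TSC22D3 had 7. SGK1 had 2, DUSP1 had 1, and PER1 and the MYC gene had 0. At TSC22D3 the Dex libraries had MED1 peaks in 11, 11 and 9 regions and each Veh library in 1.

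No other list passed for MED1. Genes near Dex-only regions numbered 6 of 40 MYC core targets, 4 of 26 estrogen receptor targets, 10 of 30 luminal genes, 17 of 35 mesenchymal and basal genes (13.4 expected), 4 of 13 AP-1 genes, 7 of 22 inflammatory genes, 3 of 22 cell cycle genes, 5 of 18 clock and metabolic genes, 3 of 20 housekeeping genes and 6 of 26 markers of other tissues, each with an adjusted permutation p of 1. Fisher's exact test without matching also called the mesenchymal and basal list (adjusted p = 0.00232). Near Veh-only regions lay 0 glucocorticoid targets against 2.35 expected, and the strongest Veh-only regions were those near EPCIP, PSG9, UGT1A6, SMAD6 and TP63, at mean percentiles of 62.3 to 66.4. The Veh-only regions of the remaining lists numbered at most 2 per list.

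Dex-only MED1 regions lay at gene ends in 8.42% of cases, against 35.4% of the regions in all 6 libraries (Fisher's exact p = 1.73e-294), and their median percentile was 47.2. MED1 lists held 52308 ± 3024 peaks after Dex and 46203 ± 4729 after vehicle (SD, n = 3 each, exact permutation p = 0.2). Gene-end shares of 25.1% ± 0.769 and 27.1% ± 1.95 overlapped between groups (SD, n = 3 each, exact permutation p = 0.2), and differed by -0.345 percentage points with lists of equal length. Without Veh replicate 1, the shortest MED1 list, the difference in peaks, Dex minus Veh, was 3440 in place of 6105 and that in gene-end share was -0.827 in place of -1.95 percentage points. With lists of equal length there were 2754 Dex-only and 673 Veh-only regions, and with windows around summits 4019 and 1039. Without Dex replicate 3 there were 5744 Dex-only and 917 Veh-only regions, and leaving out any 1 library gave 600 to 1550 Veh-only regions. The other 9 splits gave at most 841 group-only regions in all, against 4269 for the split by treatment. No untreated MED1 libraries were used here, so no background without Dex was measured for MED1.

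**Figure D4:**
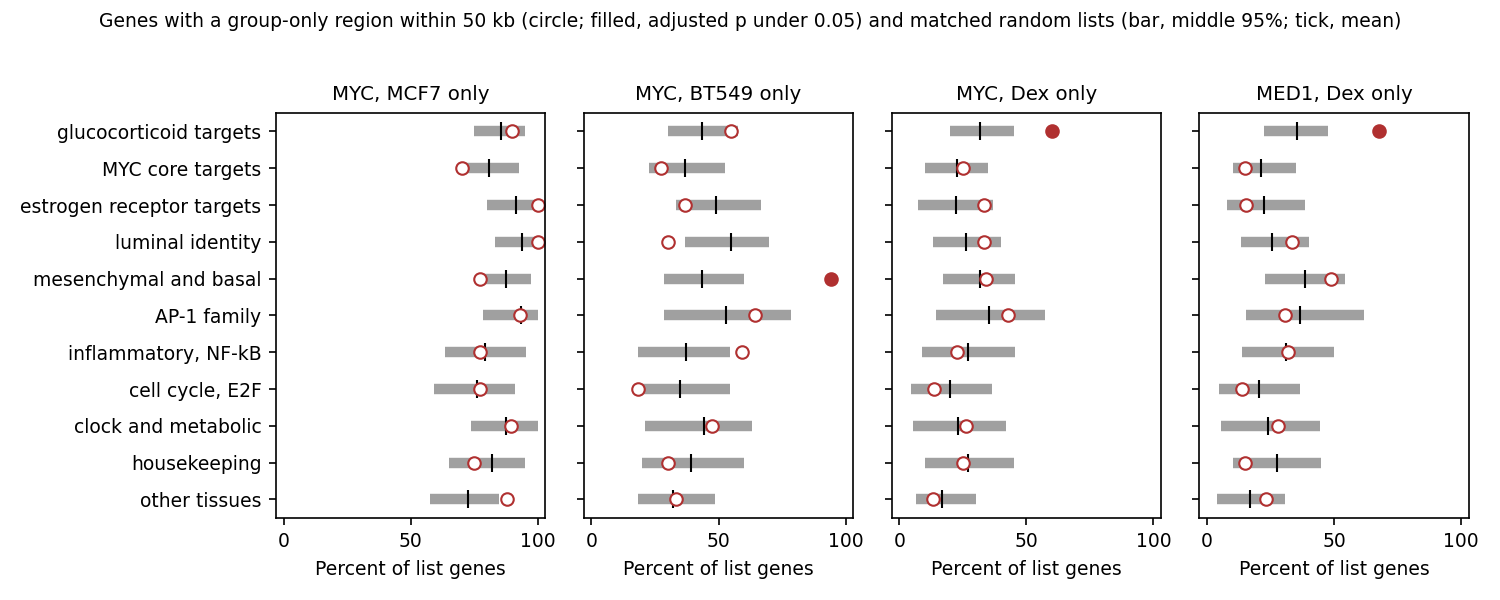
Percent of the genes of each list (horizontal axis) that lay within 50 kb of a group-only region (circles, filled where the adjusted permutation p was under 0.05), with the mean (tick) and the middle 95% (grey bar) of 10000 matched random lists. Glucocorticoid targets stand out for Dex-only regions of MYC (24 of 40, a call lost with windows of 20 kb and with lists of equal length) and MED1 (27 of 40, kept in both), and mesenchymal and basal genes for BT549-only MYC regions (33 of 35).

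The MYC and MED1 maps of BT549 were then set side by side, to ask whether the factors occupied the same places and differed with Dex at the same places. MYC and MED1 shared most of their regions with or without Dex, and the Dex-only regions of both coincided more often than independent lists would. With vehicle, 75.6% of 44585 MYC regions present in at least 2 of 3 libraries overlapped a MED1 region of the same kind, and with Dex 71.3% of 54260 did. Conversely, 86.1% of MED1 regions with vehicle and 85.4% with Dex overlapped a MYC region. In the common set of 89239 regions, 2435 were Dex-only for MYC and 3741 for MED1, and 781 were Dex-only for both, where independent lists would share 102 (odds ratio 13.4). FKBP5 had 7 and 8 Dex-only regions for MYC and MED1, and ZBTB16 had 8 and 11.

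Restricted to the 50721 regions that held peaks of both factors, the overlap of 781 stood against 93.8 for independent lists (odds ratio 19.6). In this set 2 regions were Dex-only for one factor and Veh-only for the other. Of the Dex-only MYC regions, 76.8% had no MED1 peak in any Veh library, and 31.8% had none in any Dex library. A MED1 peak in all 3 Dex libraries was held by 43.9%. Of the Dex-only MED1 regions, 77.3% had no MYC peak in any Veh library, 26.7% had none in any Dex library and 41.1% had one in all 3 Dex libraries. With lists of equal length 359 regions were Dex-only for both against 31.4 for independent lists. As regions of like strength need not be independent, a closer expectation was added after the results were seen: of the 1068 Dex-only MYC regions that held MED1 in all 3 Dex libraries, 781 were Dex-only for MED1, against 89.2 (middle 95% of draws 72 to 107) for other regions with both factors in all Dex libraries, matched on the percentiles of both and on width. The labels do not say whether MYC and MED1 libraries share chromatin or input, and neither expectation allows for that.

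The GR lists gave a map of receptor positions in BT549, from libraries whose title and treatment tag contradict each other, so that whether these cells had received Dex is not known. GR regions present in at least 2 lists lay near several known glucocorticoid targets and mostly at regions that MYC and MED1 held with and without Dex. Of the regions found in all 3 lists, 51.5% lay at MYC regions of vehicle-treated cells. Peaks of any GR list seldom lay at Dex-only or Veh-only regions. The 3 lists held 2527, 4241 and 2538 peaks, and 927 of their 8153 merged regions appeared in at least 2 lists and 194 in all 3. Their pairwise Jaccard index, the shared part of the merged regions of a pair of lists, averaged 0.0749, against 0.753 among the MYC Veh libraries in the merge with the Dex libraries. Of 23 glucocorticoid targets with any GR peak nearby, 10 had a GR region present in at least 2 lists against 3.91 expected (adjusted permutation p = 0.0198).

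These 10 genes were PER1, SGK1, ZBTB16, CEBPB, CRISPLD2, DDIT4, PIK3R1, RASD1, SERPINE1 and SLC19A2. FKBP5 had no GR peak in any list, and the GR regions near TSC22D3, KLF9, DUSP1 and MYC were each found in 1 list. The other lists did not pass (adjusted permutation p = 1 for each), with 1 MYC core target, 3 estrogen receptor targets, 2 luminal, 5 mesenchymal and basal, 1 AP-1, 0 inflammatory, 1 cell cycle, 0 clock and metabolic, 1 housekeeping and 1 other-tissue gene having a GR region. The strongest GR regions present in all 3 lists lay near ANO1, CCDC200, UBR3, KMT5B, KIF13B, DUX4, ENTPD6, DOCK1 and THOC2, and 70.6% of the regions found in all 3 lists lay outside genes. The region near ANO1 lay on chromosome 11 (70196176 to 70196618).

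Of the GR regions present in at least 2 lists, 83.9% overlapped a MYC region of vehicle-treated BT549 cells and 84.1% one of Dex-treated cells, and the shares for MED1 were 83.9% and 84.0%. In MCF7 the share was 46.4%. Among the regions found in all 3 GR lists the order turned, with 51.5% at MYC regions of vehicle-treated BT549 and 64.9% at MYC regions of MCF7. BT549-only MYC regions overlapped a GR peak of any list in 19.5% of cases, MCF7-only regions in 0.111%, and regions in all 6 libraries in 14.1% (Fisher's exact p = 2.97e-30 for BT549-only against all 6). Of the 2711 Dex-only MYC regions 12 (0.443%) overlapped a GR peak, against 13.8% of the regions in all 6 libraries (Fisher's exact p = 3.30e-145). For MED1 the counts were 15 of 3824 (0.392%) against 18.8% (Fisher's exact p = 7.08e-288). Veh-only regions also held few GR peaks, with 0 of 61 for MYC and 5 of 445 (1.12%) for MED1. A low share of GR peaks was therefore not particular to Dex-only regions.

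MYC peaks that overlapped a GR region made up 1.27% ± 0.0851 of the Dex lists and 1.58% ± 0.0440 of the Veh lists (SD, n = 3 each, exact permutation p = 0.1). With lists of equal length the difference, Dex minus Veh, was 0.000698 percentage points and had turned sign (exact permutation p = 1). MED1 peaks at GR regions made up 1.48% ± 0.0871 and 1.69% ± 0.174 (SD, n = 3 each, exact permutation p = 0.2), a difference of -0.204 percentage points that was -0.106 without Veh replicate 1 and -0.00408 with lists of equal length (exact permutation p = 0.6). The number of GR regions covered was 780 ± 0.577 by MYC Dex libraries and 778 ± 0.577 by MYC Veh libraries (SD, n = 3 each, exact permutation p = 0.1).

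**Figure D5:**
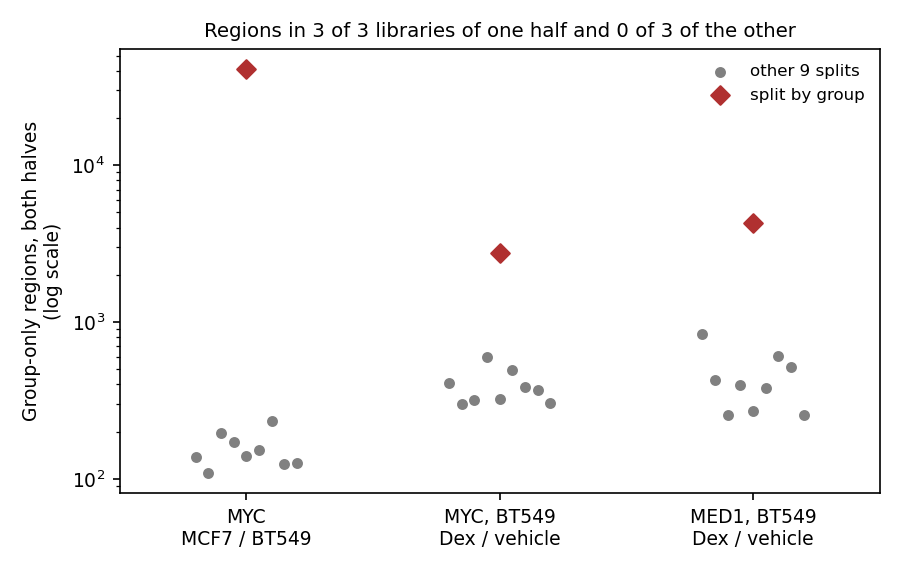
Total number of group-only regions (vertical axis, log scale) when the 6 libraries of a comparison are split by group (red diamonds) and in the other 9 ways (grey points). The splits by group give 40822, 2772 and 4269 regions, and the highest other splits give 234, 597 and 841.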

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

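The tests on matched regions in this part were chosen before their results were seen, after the low share of GR peaks at Dex-only regions had been noticed.

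The 3 GR lists titled Veh and tagged Dex drew attention because they held signal outside the human genome. On chromosome arms of the fruit fly they held 1636, 1867 and 2590 peaks, of 2487, 2717 and 3606 peaks in all. None of the other 21 lists held a peak on these arms. What these peaks stand for was not tested, and the lists entered no comparison.

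Like the Veh-only regions, the regions that MYC or MED1 held only with Dex carried few GR peaks. If these regions were only too weak for the short GR lists, regions held in all 6 libraries and matched on strength would carry as few, but 83.7 of 2711 matched MYC regions did (middle 95% of random draws 68 to 101) against 12 observed, and 357 of 3824 matched MED1 regions did (325 to 393) against 15 observed. At like strength within the MYC or MED1 lists, Dex-only regions thus still held fewer GR peaks. The draws were matched neither on width nor on GR signal, so weak GR signal at Dex-only regions cannot be excluded. Regions in all 6 libraries had a median width of 1072 bp against 529 bp for Dex-only MYC regions, and 1261 bp against 741 bp for MED1. Still open are a difference in treatment, since the title and the tag of these GR libraries disagree on whether the cells had received Dex, and other differences between the GR and MYC experiments, neither of which could be tested.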

How the results depend on the processing

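Counting all regions near a list's genes, and matching on strength and width for regions Dex-only for both factors, were chosen after the results were seen; every other alternative was planned. Depth is unknown, so no result could be tested at equal depth, and lists of equal length stood in for it. With lists of equal length the counts fell from 30653 to 13222 MCF7-only regions, from 2711 to 1041 Dex-only MYC regions, from 3824 to 2754 Dex-only MED1 regions and from 781 to 359 regions that were Dex-only for both factors, and rose from 61 to 277 Veh-only MYC and from 445 to 673 Veh-only MED1 regions. MYC regions at MED1 regions made up 78.1% with vehicle and 78.5% with Dex at equal lengths, and 66.0% and 61.8% with summit windows. The difference in MYC peaks at GR regions turned to 0.000698 percentage points at equal lengths (exact permutation p = 1), and that in MED1 peaks fell to -0.00408 (exact permutation p = 0.6). Veh-only regions numbered 408 for MYC and 1039 for MED1 with summit windows, and 291 for MED1 at the stricter threshold. The causes of these changes were not tested beyond the construction of each alternative.

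Leaving out 1 library at a time, Dex-only regions ranged from 3504 to 5226 for MYC and from 4328 to 5744 for MED1, and Veh-only regions from 110 to 207 and from 600 to 1550, since a rule over fewer libraries is easier to meet. MCF7-only and BT549-only regions ranged from 30843 to 35648 and from 10441 to 14473. Dex-only regions outnumbered Veh-only regions in every alternative run, for both factors. Peak numbers and gene-end shares kept their direction in every alternative, but without MED1 Veh replicate 1 the MED1 differences fell to 3440 peaks and -0.827 percentage points, and with 3 libraries or fewer per group their p-values say nothing about stability.

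For the cell lines 1 list test passed in the planned analysis, against 4 with gene windows of 20 kb, 3 with Fisher's test, 3 at equal lengths and 6 with region counts; mesenchymal and basal genes near BT549-only regions passed in all of these. For MYC with Dex 1 list passed, against 0 with windows of 20 kb and 0 at equal lengths, where fewer regions were tested. For MED1 1 list passed, against 2 with Fisher's test. Glucocorticoid targets passed for MED1 in every alternative. Mesenchymal and basal genes had 28 Dex-only MED1 regions against 28.0 expected with region counts, where the planned count of genes was above its expectation.

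In all, 19 values turned direction, 18 of them at single genes or lists. At equal lengths MCF7-only against BT549-only regions became 3 against 4 at KLF6, 2 against 3 at COL5A1 and EHF, 0 against 1 at COL1A1 and NCL, 1 against 3 at SDHA, 6 against 9 at NSMCE2, 1 against 2 at OLFML2A and 1 against 4 at E2F1, and BHLHE41 had 0 BT549-only against 1 MCF7-only region; GRHL2 had 1 Dex-only against 2 Veh-only MED1 regions. At the stricter threshold SDHA had 3 against 4, NSMCE2 6 against 7, BHLHE41 0 BT549-only against 1, and S100A4 0 Veh-only MED1 regions against 1. TFAP2A had 3 to 4 MCF7-only regions over the left-out libraries, and 3 against 4 BT549-only without BT549 replicate 3; GRHL2 had 2 to 5 Dex-only MED1 regions, and 2 against 3 without MED1 Dex replicate 2. Summit windows turned none of the gene counts. Of the gene counts at equal lengths, 112 moved by more than 1.5 times or to or from 0, 11 turned and 124 stayed within 1.5 times. At the stricter threshold 64 moved, 4 turned and 179 stayed, and with summit windows 25 moved and 222 stayed. When a library was left out 118 moved, 2 turned and 1362 stayed, each gene being counted once per library left out. Counts at single genes from the full lists thus often did not hold at equal lengths.

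Any pairing of the libraries by replicate number was weak. The correlations between same-numbered libraries were 0.0165, 0.00422 and 0.0356 for the cell lines, 0.0358, 0.0270 and 0.0235 for MYC with Dex, and 0.0798, 0.0343 and 0.0994 for MED1, all positive and under 0.1. In both Dex comparisons every library correlated best with its own number, which is a hint from the data and not from the design. A batch shared by libraries of the same number is therefore not excluded. With the replicate block, same-numbered pairs differed by 16416 and 3255 regions on average for MYC with Dex against 16688 and 3528 for pairs with different numbers, by 15064 and 7748 against 15881 and 8565 for MED1, and by 47249 and 18483 against 47265 and 18499 for the cell lines. Exact sign-flip tests over 3 pairs cannot go below 0.25, so no call could change. Comparisons between GR groups and motif counts were not run.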

Other observations

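The windows around other strong MCF7-only regions, the region counts near glucocorticoid targets, the ratios at equal list lengths, the count of vehicle against untreated regions, the covered lengths and the other splits were tests chosen only after the results they bear on had been seen.

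Outside the fixed lists, several genes had Dex-only regions of both factors within 50 kb; they were chosen after their values were seen, from those with the largest sums of both counts. KCNB1, a potassium channel gene, had 8 Dex-only MYC and 14 Dex-only MED1 regions. GSE1 had 3 and 12, LPP had 2 and 13, SLC45A4 had 5 and 10, the collagen gene COL23A1 had 8 and 6, the proteoglycan gene GPC6 had 6 and 8, and the kinase gene RPS6KA2 had 5 and 8. FOXO3, a transcription factor gene of insulin signalling, had 5 and 7, and PYGB, which encodes the brain form of glycogen phosphorylase, had 8 and 4. None of these 9 genes had a Veh-only region of either factor, whereas KCNMA1, with 5 and 9 Dex-only regions, also had 2 Veh-only MED1 regions. Such absence says little, as only 55 of 19970 genes had a Veh-only MYC region nearby and 525 a Veh-only MED1 region. The counts were not set against an expectation for gene length or for the number of merged regions nearby.

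Some of the strongest regions recurred between maps. The region near MIOS on chromosome 7 and the one in GNG12 on chromosome 1 were among the 10 strongest Dex-only regions of both MYC and MED1. The third strongest BT549-only MYC region, in KIF13B on chromosome 8 (29195408 to 29196178), contained the sixth strongest region shared by all 3 GR lists (29195658 to 29196116). Among MYC libraries of BT549, the Jaccard index, with untreated and vehicle libraries merged together, averaged 0.708 among untreated libraries, 0.742 among vehicle libraries and 0.633 between these sets.

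Dex-only regions outnumbered Veh-only regions for both factors, and longer Dex lists are not the whole cause, since the ratio at equal lengths was 3.76 for MYC and 4.09 for MED1. For MYC a difference between library sets that needs no Dex may account for the number. Vehicle against untreated cells gave 3815 Veh-only regions, more than the 2711 Dex-only ones, and a ratio at equal lengths of 2.09. These sets also differ in their peak calls, with highest folds of 81.0 to 116 in vehicle lists and 30.8 to 33.6 in untreated lists. In Dex lists the highest folds were 121 to 140, so vehicle against untreated may hold a difference that Dex against vehicle lacks. List length alone does not account for the Dex-only regions at glucocorticoid targets, since at equal lengths 25, counted once for each target nearby, lay there against 5.97 expected (middle 95% of matched random lists 2 to 12). Counted as genes the call ended at equal lengths, with 10 against 5.11 (1 to 9) where the full lists gave 24 against 12.7, as fewer Dex-only regions were left (1041 in place of 2711). The sets made without Dex do not settle it: 22 of 39 glucocorticoid targets lay near Veh-only regions of vehicle against untreated cells (13 to 23), but counted as regions there were 48 against 33.4 (22 to 46) with all peaks and 23 against 13.9 (7 to 22) at equal lengths, both above their range, so part of the excess may not need Dex. Depth or yield cannot be told apart from treatment, as the lists hold neither and the Dex lists covered 1.30 times the length of the Veh lists, and an effect of Dex on MYC binding stays open as well.

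All 10 of the strongest MCF7-only MYC regions lay on chromosomes 17 and 20, in 3 windows that reach 1 Mb to either side of them. A gain of DNA copies in MCF7 was tested and stays open: the 66 regions in these windows that all 6 libraries held had a median percentile of 95.2 in MCF7 against 72.9 elsewhere, and of 68.0 against 71.8 in BT549, a shift of 26.2 points (random windows -13.8 to 17.2, permutation p = 0.005). The windows were placed by their high ranks in MCF7, however. Windows around the other regions among the strongest 1% of MCF7-only regions gave shifts of -3.66 to 27.0 (middle 95%, median 10.5), which just includes the value seen. The permutation p was 0.03, as it counts all shifts of at least that size, whereas the range is cut at both ends. These other windows were kept out of the 3 windows only, so they may hold copy gains themselves. The comparison therefore cannot decide between a gain of copies and what this choice of windows brings. The lists hold no input signal, so copy number itself was not measured, and a stronger activity of these chromosome parts in MCF7 was not tested. No like test was made around the strongest BT549-only regions. The windows held 241 MCF7-only regions, 0.786% of all, so they bear on the ranking and little on the count.

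With 10 splits of 6 libraries, the splits are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many group-only regions: 40822 against a highest other of 234 for the cell lines, 2772 against 597 for MYC with Dex, and 4269 against 841 for MED1.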
